A study of Sus scrofa with 12 samples.

How the data were processed

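RNA of denuded pig oocytes was sequenced at 0, 12, 28 and 44 h of in vitro maturation, with 3 libraries at each time, and the deposited gene table was analysed here. Per the labels, RNA was isolated with an AllPrep micro kit, libraries were made with the SMARTer Stranded Total RNA-Seq Pico kit, and sequencing was on a NovaSeq. The authors' processing notes name the genome build Sscrofa11.1 and DESeq2; the aligner and the rule for reads that match several genes are not given, so genes with near-identical copies and overlapping genes are uncertain. Column names put all libraries on the same lane.

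Per the file headers, the deposited table gives for each library the total counts of each gene, which the authors made by assigning reads to annotated genes; these whole numbers were the input here. The deposited RPKM values are, per the file headers, the same counts scaled by library and gene length, and they were used only to derive a gene model length. The authors' log2 fold changes and FDR p-values for 6 pairwise comparisons, deposited in the same table, were used only to count shared calls. The deposited TPM and CPM columns were not used.

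The table held 28965 genes. A symbol was present for 16246 of them, 785 more were named from an Ensembl name table, and 11934 kept their identifier. Libraries were matched to samples by time and replicate number in the titles, and none of the 66 pairs of libraries had identical counts. Genes were kept by filterByExpr with a minimum count of 10, which left 12977. Counts were scaled by TMM (factors 0.979 to 1.02) and fitted in edgeR 4.0.16 under R 4.3.3 with 1 mean per time, all 12 libraries, robust estimation of the spread and 8 residual degrees of freedom. Contrasts were tested with edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes of a comparison, at a threshold of 0.05. The comparisons were 12 h with 0 h, 28 h with 12 h, 44 h with 28 h, 44 h with 0 h, 28 h with 0 h, and any change over the 4 times. Printed CPM values are means and SD of the 3 libraries, and fold changes come from the fit with edgeR's default prior; list tests used log2 CPM with a prior count of 2. The biological coefficient of variation was 10.6%.

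Gene lists, 22 in number, were written before the data were examined; 21 had at least 5 tested members. The list of small nuclear and small nucleolar RNA genes had 0 tested members, so edgeR, DESeq2 and limma-voom gave no test of it. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) over 84 list and comparison pairs together, and again with an estimated correlation and with fry. The named genes were set by a rule written beforehand: in each of the 4 main comparisons, the 6 largest rises and 6 largest falls among called genes with a symbol, a mean of at least 10 CPM in the higher group and no overlap between groups; up to 2 members of each list that rose and 2 that fell, by smallest adjusted p; and a panel of 12 genes. Of that panel, HAS2 and NPM2 were not analysed here, since they had no tested row. Genes named outside the rule are said to be, where they appear or at the head of their section. Results of some single genes are not reported here.

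Alternatives were other scalings (RLE, upper quartile, library totals alone, and without mitochondrially encoded genes), no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, fits of only the 2 times compared, a replicate block, and leaving out each library in turn; a fit without robust estimation was added after the data were seen. The pipeline was tested on simulated data built from 12806 genes of these libraries. At 3 libraries against 3 it recovered 43.3% of genes changed 1.3-fold, 86.6% of those changed 2-fold and 95.5% of those changed 4-fold, and 9.09% of its calls were unchanged genes. With no gene changed, edgeR made 0 calls. Known log2 changes lay within 2 standard errors for 96.6% of the 177 changed genes with a log2 CPM above 3. A shifted list had a camera adjusted p of 4.3e-47 and a random list 0.234. The simulated genes varied independently, so this cannot test the camera p-values of lists whose genes vary together. Shifts common to a whole library were not simulated either, so their effect on the calls was not tested. Totals of 21877235 to 26015373 counts per library leave counting error small for genes at or above 10 CPM.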

Results

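Gene expression was measured in pig (Sus scrofa) oocytes stripped of their surrounding cumulus cells. Oocytes were sampled at 4 times of maturation in vitro, 0, 12, 28 and 44 h, with 3 libraries at each time. The series asks whether pig oocytes that mature in a medium of defined composition still change their RNA content and transcribe genes. Each library held between 21877235 and 26015373 gene counts, and the deepest library had 1.19 times the counts of the shallowest. By replicate, the totals were 23739391, 25744280 and 24221249 at 0 h (replicates 2, 3 and 4), 24273227, 23055288 and 24933230 at 12 h (1, 3 and 5), 21877235, 24679147 and 24436520 at 28 h (2, 3 and 4), and 26015373, 25536875 and 25041494 at 44 h (1, 2 and 4). Of 28965 genes in the count table, 17814 had a count in at least 1 library and 12977 passed the filter on low counts and were tested. Levels below are CPM, counts scaled to a common library size, ± SD with n = 3 libraries per time. They are shares of a library, and the labels name no added standard RNA. The labels do not say whether the 3 libraries of a time came from separate animals or cultures, so p-values measure only the spread between these libraries.

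DNMT1, the maintenance DNA methyltransferase (ENSSSCG00000013659, Sscrofa11.1 chromosome 2, 68981564 to 69029919), took 3.58 ± 0.193% of all counts at 0 h and 3.12 ± 0.236% at 44 h. BMP15, a growth factor secreted by the oocyte, stood at 5003 ± 420 CPM at 0 h, and WEE2, an oocyte kinase that holds back CDK1, at 1979 ± 35.2 CPM. Mitochondrially encoded genes took 1.06 ± 0.0595% of counts at 0 h, 0.919 ± 0.373% at 12 h, 0.706 ± 0.225% at 28 h and 0.658 ± 0.125% at 44 h. In a multidimensional scaling of the libraries, dimension 1 ran from the 0 h to the 44 h libraries. Replicate 5 of 12 h stood apart on dimension 2, at -1.55, and its mitochondrially encoded share was 1.35%.

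**Figure D1:**
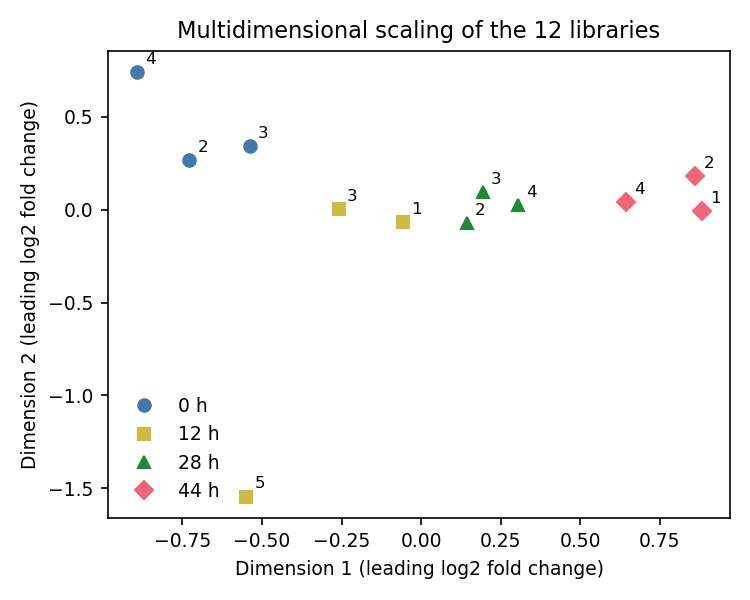
Multidimensional scaling of the 12 libraries, with both axes in leading log2 fold change; symbols give the time and numerals the replicate. Replicate 5 of 12 h lies at -1.55 on dimension 2.

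The comparison of 12 h with 0 h asks which transcripts change early in maturation. Transcripts of KIF1C, a kinesin motor (ENSSSCG00000017900, chromosome 12, 51897763 to 51924437), rose from 3.46 ± 0.458 to 28.3 ± 3.88 CPM, an 8.17-fold rise. PDK4, a kinase that switches off pyruvate dehydrogenase (ENSSSCG00000015334, chromosome 9, 75246002 to 75260134), rose from 1.42 ± 0.679 to 10.7 ± 4.38 CPM. PALM2AKAP2 and AKAP12, both with anchoring domains for protein kinase A, rose from 18.7 ± 2.06 to 50.1 ± 4.77 CPM and from 16.5 ± 1.87 to 33.2 ± 7.22 CPM. MAP1B, a microtubule-associated protein (ENSSSCG00000016974, chromosome 16, 48403526 to 48498896), rose from 79.9 ± 8.86 to 165 ± 10.2 CPM, and TP53INP2, which acts in autophagy, from 23.0 ± 0.815 to 42.4 ± 3.08 CPM. RSPO2, a secreted activator of Wnt signalling, fell from 208 ± 9.09 to 167 ± 5.11 CPM, and CALD1, an actin-binding protein, from 16.3 ± 1.72 to 10.7 ± 0.728 CPM. C1orf115 fell from 11.9 ± 1.57 to 6.32 ± 0.262 CPM. IGF1, a growth factor named here after its values were seen, fell from 0.647 ± 0.231 to 0.0144 CPM.

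None of the gene groups fixed beforehand had more than 1 member past the test between 0 and 12 h. That member was PDK4, in the group of 33 glycolysis, pentose phosphate and pyruvate genes. In the other 20 groups, edgeR called 0 of 789 members, where 160 had an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 0. Among 58 cytosolic ribosomal protein genes, 28 were lower when adjusted over the list alone and the median log2 fold change was -0.25. RPL10A, for example, stood at 68.0 ± 9.18 CPM at 0 h and at 50.6 ± 6.88 CPM at 12 h. The ribosomal list ranked low among all genes by camera, which tests a list against all other genes (Benjamini-Hochberg adjusted p = 9.7e-16 with the preset correlation, adjusted p = 0.388 with an estimated correlation). The 65 nuclear-encoded respiratory chain genes had a median of -0.22 and 0 members adjusted over the list alone (adjusted p = 1.21e-12 by camera, adjusted p = 0.43 with an estimated correlation). Across 12563 genes, log2 fold changes at 12 h rose with gene model length (Spearman correlation 0.21), and lists were not matched on length at this step.

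Smaller list shifts at 12 h rested in part on single libraries. For the 17 oocyte growth and zona pellucida genes, 7 were lower adjusted over the list alone (camera adjusted p = 0.00223, adjusted p = 0.334 with an estimated correlation, and 0.0503 without 12 h replicate 1). For 23 histone genes the camera adjusted p was 0.00488 in the lower direction (adjusted p = 0.504 with an estimated correlation), which became 0.161 without 0 h replicate 2 and 0.0589 without 12 h replicate 1. The 33 antioxidant and redox genes also ranked low (camera adjusted p = 0.0121, adjusted p = 0.504 with an estimated correlation), and the call ended without 0 h replicate 2 (0.151) or 12 h replicate 3 (0.0539). The 76 DNA methylation and histone modification genes ranked high (camera adjusted p = 0.00961, adjusted p = 0.504 with an estimated correlation, and 0.0668 without 12 h replicate 1). Markers of cumulus and granulosa cells had 0 of 24 members called, 1 adjusted over the list alone; INHBA, an inhibin subunit, stood at 1.503 ± 0.718 CPM at 0 h and 4.02 ± 0.338 CPM at 12 h.

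By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 27 genes differed between 12 h and 0 h, 23 of them higher and 4 lower at 12 h, and 1461 genes had an unadjusted p under 0.05. KIF1C had a log2 fold change of 3.03 (SE 0.15), with an adjusted p of 7.84e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scaling by library totals alone gave 23 higher and 10 lower genes. The balance of rises and falls depended on the libraries and the tool. Without 0 h replicate 3 the count was 261 genes, of which 159 (60.9%) were lower, so that falls outnumbered rises. Without 0 h replicate 2 it was 18 higher and 2 lower, and without 12 h replicate 1 all 21 called genes were higher. DESeq2 gave 43 higher and 25 lower genes, and edgeR without a filter on low counts 36 and 28. Among the genes named above, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment no longer called C1orf115 without 12 h replicate 1 (adjusted p 0.0512). IGF1 was not called in that fit either, since no lower gene was. RSPO2 was lost without any of 4 libraries, 0 h replicates 2 and 4 and 12 h replicates 1 and 3 (edgeR adjusted p from 0.0626 to 0.161), and CALD1 without any of 8 (0 h replicate 4, each 12 h and 28 h library, and 44 h replicate 2; edgeR adjusted p from 0.0534 to 0.209).

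**Figure D2:**
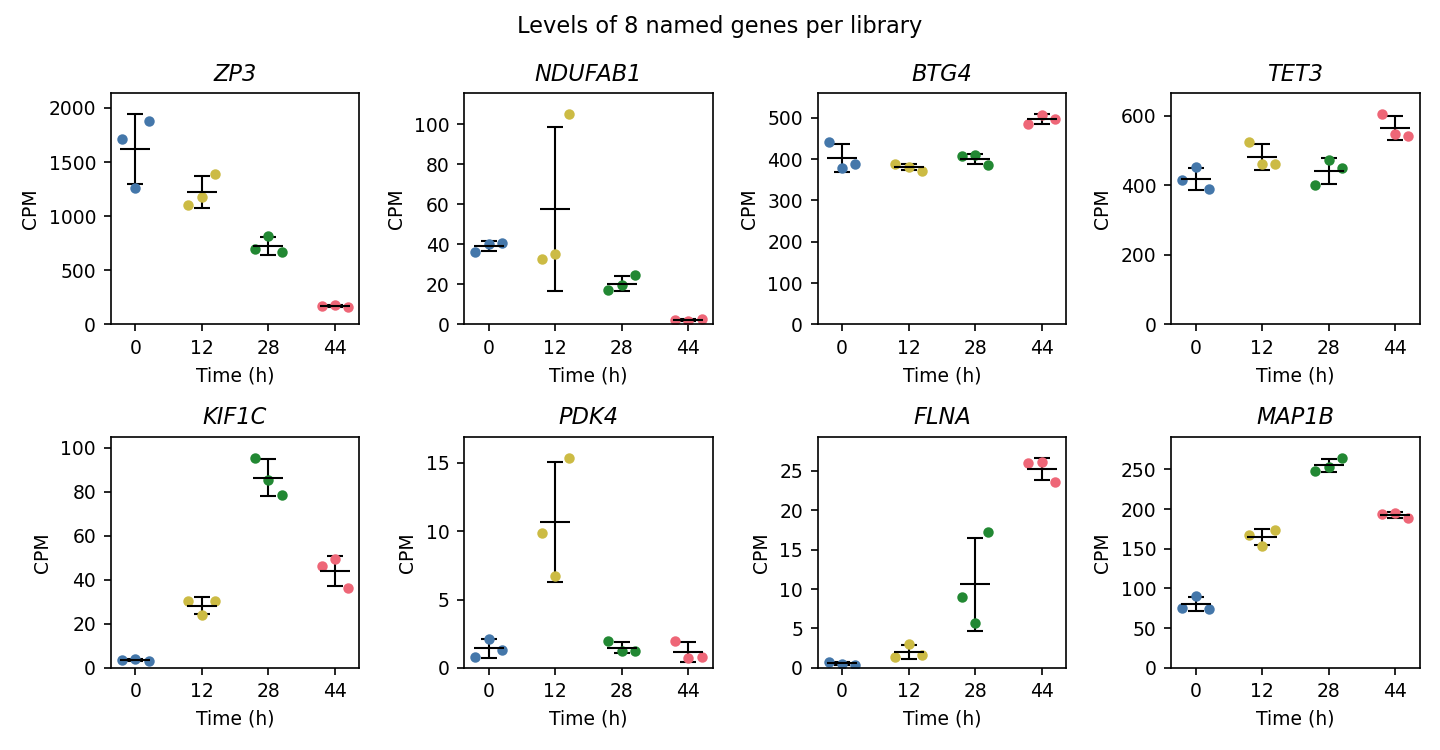
Levels of 8 named genes in each library (CPM, linear axes from 0) against time of maturation; points are libraries, bars the mean and SD of 3. KIF1C and MAP1B were highest at 28 h, PDK4 at 12 h, and ZP3 fell from 1620 ± 319 CPM at 0 h to 169 ± 6.77 CPM at 44 h.

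The step from 12 to 28 h covers the middle of maturation. KIF1C rose further, to 86.3 ± 8.42 CPM, and MAP1B to 255 ± 8.14 CPM. ZEB2, a zinc finger repressor (ENSSSCG00000021343, chromosome 15, 7499026 to 7632655), rose from 7.61 ± 1.89 to 30.5 ± 4.28 CPM. ANTXR1, a cell surface receptor for collagen, rose from 1.83 ± 0.700 to 11.4 ± 0.960 CPM. CALD1, which had been lower at 12 h, rose to 23.7 ± 1.302 CPM. FLNA, an actin-crosslinking filamin (ENSSSCG00000033299, chromosome X, 124890142 to 124917171), rose from 2.01 ± 0.890 to 10.6 ± 5.91 CPM. PDK4 returned to 1.47 ± 0.408 CPM, a fall of 7.29-fold, and ARRDC4, an arrestin-domain protein, fell from 45.7 ± 3.04 to 17.7 ± 2.95 CPM. AKAP12 fell back to 19.0 ± 1.99 CPM. Falls were also measured for YIF1A, a transport gene of the Golgi, from 19.7 ± 3.16 to 11.2 ± 0.469 CPM, and for SLIRP, which binds mitochondrial RNA, from 14.8 ± 0.639 to 8.72 ± 0.843 CPM. Leaving out 1 library ended some of these calls in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. FLNA was lost without each 0 h library, 12 h replicate 1 or 5, 28 h replicate 2, or 44 h replicate 1 or 2 (adjusted p 0.0511 to 0.304). YIF1A was lost without 12 h replicate 5 or any 28 h library (0.0506 to 0.0884), AKAP12 without 12 h replicate 1 or 5 or 28 h replicate 2 or 3 (0.0617 to 0.101), and SLIRP without 0 h replicate 2 or any 12 h or 28 h library (0.0522 to 0.317).

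Of 17 oocyte growth and zona pellucida genes, 2 fell between 12 and 28 h, or 3 adjusted over the list alone. They were the zona pellucida proteins ZP3, from 1222 ± 148 to 727 ± 82.1 CPM, and ZP4, from 1594 ± 125 to 1148 ± 119 CPM. These calls were close to the threshold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, ZP3 had an adjusted p of 0.045, and 9 single libraries ended its call (0 h replicate 2, each 12 h and 44 h library, and 28 h replicates 2 and 4; 0.0668 to 0.380). ZP4 had an edgeR adjusted p of 0.0411, and 5 libraries ended it (0 h replicate 2, 12 h replicates 3 and 5, 28 h replicates 2 and 4; 0.0638 to 0.317). Scaling by library totals alone also ended both calls.

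Of 58 ribosomal protein genes, 4 fell between 12 and 28 h, or 21 adjusted over the list alone. RPL6 fell from 114 ± 10.5 to 81.8 ± 5.77 CPM and RPL35 from 65.1 ± 7.41 to 42.2 ± 2.40 CPM. RPLP2, named after its values were seen, fell from 116 ± 7.46 to 74.7 ± 2.74 CPM, and RPL10A, likewise, from 50.6 ± 6.88 to 35.3 ± 3.09 CPM. The list ranked low (camera adjusted p = 2.53e-20, adjusted p = 0.334 with an estimated correlation). RPL6 lost its call in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without 12 h replicate 5, 28 h replicate 2 or 28 h replicate 4 (adjusted p up to 0.169). RPL35 lost it without any of 5 libraries, 12 h replicates 3 and 5 and each 28 h library (edgeR adjusted p 0.0506 to 0.209). Without 28 h replicate 2, PDK4 and ARRDC4 were the only lower genes called, so all 4 ribosomal protein calls ended.

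The respiratory chain list ranked low with 0 of 65 members called, or 4 adjusted over the list alone (camera adjusted p = 1.12e-07, adjusted p = 0.571 with an estimated correlation); 13 had an unadjusted p under 0.05 in edgeR, DESeq2 called 3 and limma-voom 0. All 13 mitochondrially encoded genes had lower means at 28 h, and edgeR, DESeq2 and limma-voom called 0 of them, with 0 at an unadjusted p under 0.05. Their list had a camera adjusted p of 0.00153 (adjusted p = 0.758 with an estimated correlation), which was 0.429 without 12 h replicate 5 and 0.612 without 28 h replicate 4. Histone genes ranked low (camera adjusted p = 0.0454, adjusted p = 0.677 with an estimated correlation), and 7 single libraries ended that call (0 h replicate 4, 12 h replicate 3, each 28 h library, and 44 h replicates 1 and 2; up to 0.457). Markers of cumulus and granulosa cells ranked high, with 0 of 24 called and 3 adjusted over the list alone (camera adjusted p = 0.0454, adjusted p = 0.651 with an estimated correlation). Upper-quartile scaling and library totals alone also ended this call. It ended too without any of 7 libraries (0 h replicate 4, each 12 h library, 28 h replicate 4, and 44 h replicates 2 and 4; up to 0.610). The 19 markers below 10 CPM at 0 h summed to 64.4 CPM in 28 h replicate 4, against 44.3 and 46.5 CPM in 28 h replicates 2 and 3. In all, 18 lists had 0 of 714 members called by edgeR between 12 and 28 h, where 61 had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0.

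Between 28 and 12 h, 34 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 14 higher and 20 lower at 28 h, and 811 had an unadjusted p under 0.05. Scaling by library totals alone gave 12 higher and 11 lower genes. The count depended on single libraries: it was 8 (6 higher, 2 lower) without 28 h replicate 2, 20 (8, 12) without 28 h replicate 3, 11 (8, 3) without 28 h replicate 4, 14 (9, 5) without 12 h replicate 3, 11 (7, 4) without 12 h replicate 5 and 52 (16, 36) without 0 h replicate 3. Without 12 h replicate 1, 8 genes were higher and 17 lower. DESeq2 gave 19 higher and 50 lower genes, and a fit of only these 2 times 15 and 36.

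**Figure D3:**
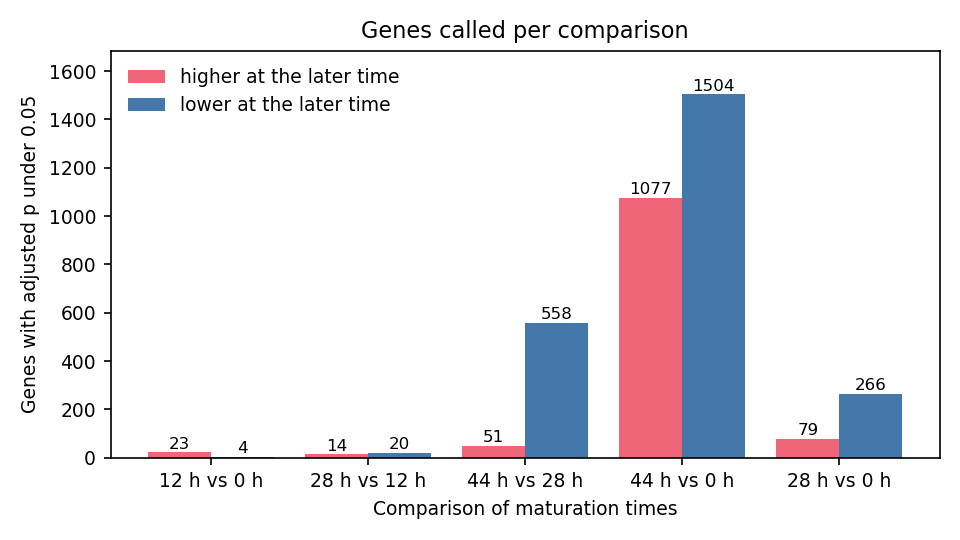
Number of genes with an adjusted p under 0.05 in each comparison, as bars from 0 for genes higher and genes lower at the later time. Between 28 and 44 h, 51 genes were higher and 558 lower.

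The step from 28 to 44 h, the last part of maturation, was marked by losses. ZP3 (ENSSSCG00000007691, chromosome 3, 9934761 to 9944941) fell from 727 ± 82.1 to 169 ± 6.77 CPM, or 4.30-fold, and ZP4 from 1148 ± 119 to 499 ± 64.8 CPM. NDUFAB1, the mitochondrial acyl carrier protein (ENSSSCG00000010795, chromosome 3, 22619492 to 22635288), fell from 20.4 ± 3.88 to 2.19 ± 0.326 CPM. YIF1A fell from 11.2 ± 0.469 to 2.31 ± 0.453 CPM, PSKH1, a serine kinase, from 39.7 ± 4.91 to 10.4 ± 2.20 CPM, and PIGX, which acts in GPI anchor synthesis, from 16.9 ± 2.29 to 4.49 ± 1.07 CPM. TBL3, a factor of ribosomal RNA processing, fell from 10.7 ± 1.03 to 2.90 ± 0.208 CPM. Rises were smaller. NPM3, of the nucleoplasmin family, rose from 24.8 ± 1.11 to 34.9 ± 2.37 CPM, BTBD7 from 92.4 ± 8.77 to 123 ± 7.08 CPM and ZBTB39 from 64.3 ± 3.79 to 83.8 ± 7.36 CPM. LCOR, a nuclear receptor corepressor, rose from 83.4 ± 8.65 to 115 ± 9.75 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, NDUFAB1 was not called without 44 h replicate 1 or 2 (adjusted p 0.0601 and 0.0643) and LCOR not without 28 h replicate 2 (0.0506). Levels of NDUFAB1 did not overlap, at 17.0 to 24.6 CPM at 28 h and 1.86 to 2.51 CPM at 44 h. The fit of all libraries also holds 12 h replicate 5, where NDUFAB1 stood at 104.8 CPM, against 32.6 and 35.1 CPM in 12 h replicates 1 and 3.

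Of 58 ribosomal protein genes, 38 fell between 28 and 44 h and 0 rose, or 47 and 1 adjusted over the list alone. RPL23A fell from 138 ± 13.98 to 53.3 ± 7.65 CPM and RPL38 from 18.7 ± 3.83 to 5.87 ± 0.362 CPM. The list's median log2 fold change was -0.53 (camera adjusted p = 1.77e-32, adjusted p = 0.334 with an estimated correlation). Of 65 respiratory chain genes, 12 fell, or 24 adjusted over the list alone, among them the complex I subunit NDUFV1, from 14.4 ± 1.97 to 4.35 ± 1.45 CPM, and COX7A2L, from 236 ± 6.16 to 140 ± 18.4 CPM (camera adjusted p = 1.37e-09, adjusted p = 0.504 with an estimated correlation). Histone transcripts fell for 9 of 23 genes, or 10 adjusted over the list alone, with H2AC11 going from 145 ± 7.82 to 84.3 ± 2.89 CPM and H2BE1 from 7.66 ± 1.497 to 1.62 ± 0.270 CPM (camera adjusted p = 1.2e-05, adjusted p = 0.334 with an estimated correlation). Ribosomal protein and histone genes have near-identical copies in the genome, and how the counting treated reads that match several copies is not given, so single members are uncertain.

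Among oocyte genes, 4 of 17 growth and zona pellucida genes fell in this step, or 5 adjusted over the list alone: ZP3, ZP4, GDF9 and, named after its values were seen, ZP2, from 1136 ± 33.1 to 653 ± 89.8 CPM (camera adjusted p = 0.0106, adjusted p = 0.43 with an estimated correlation). GDF9, a growth factor of the oocyte, fell from 1247 ± 15.1 to 1078 ± 16.6 CPM. BMP15 stood at 4001 ± 170 and 3964 ± 110 CPM and did not pass. Of 17 maternal-effect genes, 2 rose and 2 fell, or 3 and 5 adjusted over the list alone. BTG4, an adaptor of the CCR4-NOT deadenylase (ENSSSCG00000015020, chromosome 9, 39208138 to 39368307), rose from 401 ± 12.5 to 497 ± 11.5 CPM. TET3, which oxidises 5-methylcytosine (ENSSSCG00000008292, chromosome 3, 68918933 to 69020986), rose from 441 ± 37.3 to 564 ± 34.4 CPM. OOEP, of the subcortical maternal complex, fell from 117 ± 6.44 to 78.5 ± 8.64 CPM and ZAR1L from 914 ± 2.52 to 692 ± 49.2 CPM. Of 59 meiotic cell cycle genes, 2 fell, the separase gene ESPL1, from 481 ± 33.3 to 380 ± 23.6 CPM, and MOS, the kinase upstream of MAP kinase, from 831 ± 37.7 to 687 ± 25.5 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, TET3 was not called without 28 h replicate 2 (adjusted p 0.0520). GDF9 was lost without any 1 of the 6 libraries of these times (0.0600 to 0.123), and MOS without 28 h replicate 2 or 3 or 44 h replicate 2 or 4 (0.0774 to 0.119). Upper-quartile scaling also ended the GDF9 call in edgeR.

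Genes of the transcription and protein machinery mostly fell where they passed, as did 558 of all 609 genes called in this step. Of 68 RNA polymerase II and general transcription factor genes, 2 rose and 8 fell, or 3 and 12 adjusted over the list alone. The mediator subunit MED28 rose from 567 ± 6.39 to 679 ± 16.1 CPM and the cyclin CCNT1 from 104.6 ± 5.74 to 126 ± 2.25 CPM, while GTF2F1, a TFIIF subunit, fell from 153 ± 18.2 to 84.2 ± 11.3 CPM and POLR2F, a polymerase subunit, from 15.7 ± 1.31 to 7.71 ± 1.01 CPM. Of 70 proteasome and ubiquitin conjugation genes, 7 fell, or 8 adjusted over the list alone, with PSMB7 going from 41.8 ± 4.71 to 19.8 ± 2.28 CPM. Of 72 splicing factor genes, 5 fell (7 adjusted over the list alone, where 1 also rose), SRSF6 from 38.9 ± 5.22 to 19.99 ± 1.20 CPM and SNRPA from 47.8 ± 4.31 to 34.6 ± 0.701 CPM, and, named after their values were seen, SNRPD2, DHX16 and LSM6. These lists of RNA polymerase II, proteasome and splicing genes did not pass camera (adjusted p 0.148, 0.277 and 0.263). Of 27 immediate early and heat shock genes, HSPA8, a constitutive chaperone, fell from 813 ± 60.8 to 554 ± 30.4 CPM, the Krüppel-like factor KLF2 fell from 92.9 ± 7.05 to 72.2 ± 6.64 CPM, and KLF4 rose from 51.9 ± 1.72 to 63.1 ± 3.43 CPM. Of 33 glycolysis, pentose phosphate and pyruvate genes 2 fell, or 3 adjusted over the list alone: aldolase C, ALDOC, from 149 ± 3.73 to 119.7 ± 1.59 CPM, and transketolase, TKT, from 85.1 ± 6.22 to 54.5 ± 0.955 CPM. The peroxiredoxin PRDX4 fell to 2.80 ± 0.537 CPM, the only call among 33 antioxidant genes, and CD74, of MHC class II transport, fell from 11.8 ± 1.14 to 6.44 ± 0.189 CPM, the only call among 6 blood and immune markers. The lipid droplet protein PLIN2 fell from 182 ± 1.79 to 138 ± 15.6 CPM, the only call among 55 lipid genes. CCNT1 was not called without 28 h replicate 2 or 4 or any 44 h library (edgeR adjusted p 0.0784 to 0.203).

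Several further calls between 28 and 44 h depended on single libraries in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. AGO2, an Argonaute protein, rose from 276 ± 12.3 to 335 ± 7.20 CPM and was not called without 28 h replicate 3 or 44 h replicate 1 (edgeR adjusted p 0.0665 and 0.0568). CPEB2, a regulator of translation, fell from 95.1 ± 7.87 to 74.3 ± 2.17 CPM and was not called without 28 h replicate 3 (edgeR adjusted p 0.0841). The list of 56 mRNA decay and translational control genes held 2 rises, BTG4 and AGO2, and 3 falls, CPEB2, PABPC1 and, named after its values were seen, CSTF2T. PABPC1 was not called without 28 h replicate 2 or 3 or 44 h replicate 2 or 4 (edgeR adjusted p 0.0863 to 0.128), nor was KLF2 (0.0701 to 0.142). KLF4 was lost without 0 h replicate 2, any 28 h library or 44 h replicate 1 or 2 (edgeR adjusted p 0.0566 to 0.215). In 5 lists edgeR called 0 of 87 members between 28 and 44 h, those of mitochondrially encoded, apoptosis and early embryo genes and of cumulus and stromal markers; 9 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 2. Of 76 DNA methylation and histone modification genes, TET3 rose and DOT1L, a histone methyltransferase, fell, or 1 and 0 adjusted over the list alone. That list ranked high (camera adjusted p = 0.0148, adjusted p = 0.504 with an estimated correlation), and the call ended without 28 h replicate 2 (0.122) or 44 h replicate 1 (0.0702). DOT1L went from 198 ± 21.3 to 162 ± 9.85 CPM and was lost without any of 4 libraries, 28 h replicates 3 and 4 and 44 h replicates 1 and 2 (edgeR adjusted p 0.115 to 0.221).

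In all, 609 genes differed between 44 and 28 h by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 51 higher and 558 lower at 44 h. The median log2 fold change was 0.27 among the genes that rose and -0.59 among those that fell. Without 44 h replicate 2 the count was 394 genes, 17 higher and 377 lower. The number of higher genes also moved with other single libraries: it was 12 without 28 h replicate 2, 16 without 28 h replicate 3 and 14 without 44 h replicate 1. Without 0 h replicate 3, 723 genes were called, 615 of them lower, which leaves over 2 times as many higher genes. The number of higher genes was 169 in DESeq2, beside 667 lower, and 253 in a fit of only these 2 times, beside 728 lower.

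Across the whole course, 44 h against 0 h, the largest rise among named genes of at least 10 CPM was that of FLNA, from 0.579 ± 0.194 to 25.2 ± 1.42 CPM. KIF1C rose 12.7-fold to 43.98 ± 6.76 CPM, PMF1, a kinetochore protein, from 30.4 ± 12.1 to 109 ± 12.6 CPM, and PLEC, a cytoskeletal linker, from 5.14 ± 1.32 to 15.3 ± 4.25 CPM. MAP1B reached 193 ± 3.70 CPM and PALM2AKAP2 35.3 ± 1.29 CPM. NDUFAB1 fell 17.8-fold, from 39.0 ± 2.64 to 2.19 ± 0.326 CPM. ROMO1, a mitochondrial membrane protein, fell from 16.3 ± 4.12 to 1.45 ± 0.250 CPM, ETFB, an electron transfer flavoprotein, from 13.8 ± 3.25 to 1.36 ± 0.258 CPM, and SLIRP from 17.1 ± 2.25 to 1.92 ± 0.566 CPM. YIF1A fell from 18.2 ± 0.605 to 2.31 ± 0.453 CPM. ZP3 fell 9.58-fold, from 1620 ± 319 to 169 ± 6.77 CPM (log2 fold change -3.26, SE 0.14; adjusted p 3.89e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

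Of 58 ribosomal protein genes, 52 fell and 1 rose between 0 and 44 h, also when adjusted over the list alone, with a median log2 fold change of -0.96. RPL10A fell from 68.0 ± 9.18 to 14.5 ± 1.18 CPM and RPL38 from 34.8 ± 2.63 to 5.87 ± 0.362 CPM. RPL26L1 rose from 184 ± 6.11 to 219 ± 10.5 CPM, a call that ended without 44 h replicate 1 (adjusted p 0.0578 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Camera ranked the list low (adjusted p = 8.67e-38, adjusted p = 0.334 with an estimated correlation). Of 65 respiratory chain genes, 50 fell and 0 rose, or 55 adjusted over the list alone, among them NDUFV1, from 24.5 ± 2.20 to 4.35 ± 1.45 CPM, and NDUFA11, from 17.8 ± 4.12 to 4.70 ± 0.151 CPM (camera adjusted p = 8.25e-23, adjusted p = 0.334 with an estimated correlation). The 13 mitochondrially encoded genes had a median of -0.65 and 0 calls in edgeR, 3 with an unadjusted p under 0.05, 1 call in DESeq2 and 6 in limma-voom. COX3 stood at 1046 ± 121 CPM at 0 h and 553 ± 127 CPM at 44 h. Their list had a camera adjusted p of 0.0135 (adjusted p = 0.771 with an estimated correlation), which was 0.0502 without 0 h replicate 3 and 0.0710 without 44 h replicate 1. Histone transcripts fell for 12 of 23 genes, or 13 adjusted over the list alone, H2AC11 from 189 ± 2.89 to 84.3 ± 2.89 CPM (camera adjusted p = 1.13e-06, adjusted p = 0.334 with an estimated correlation).

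**Figure D4:**
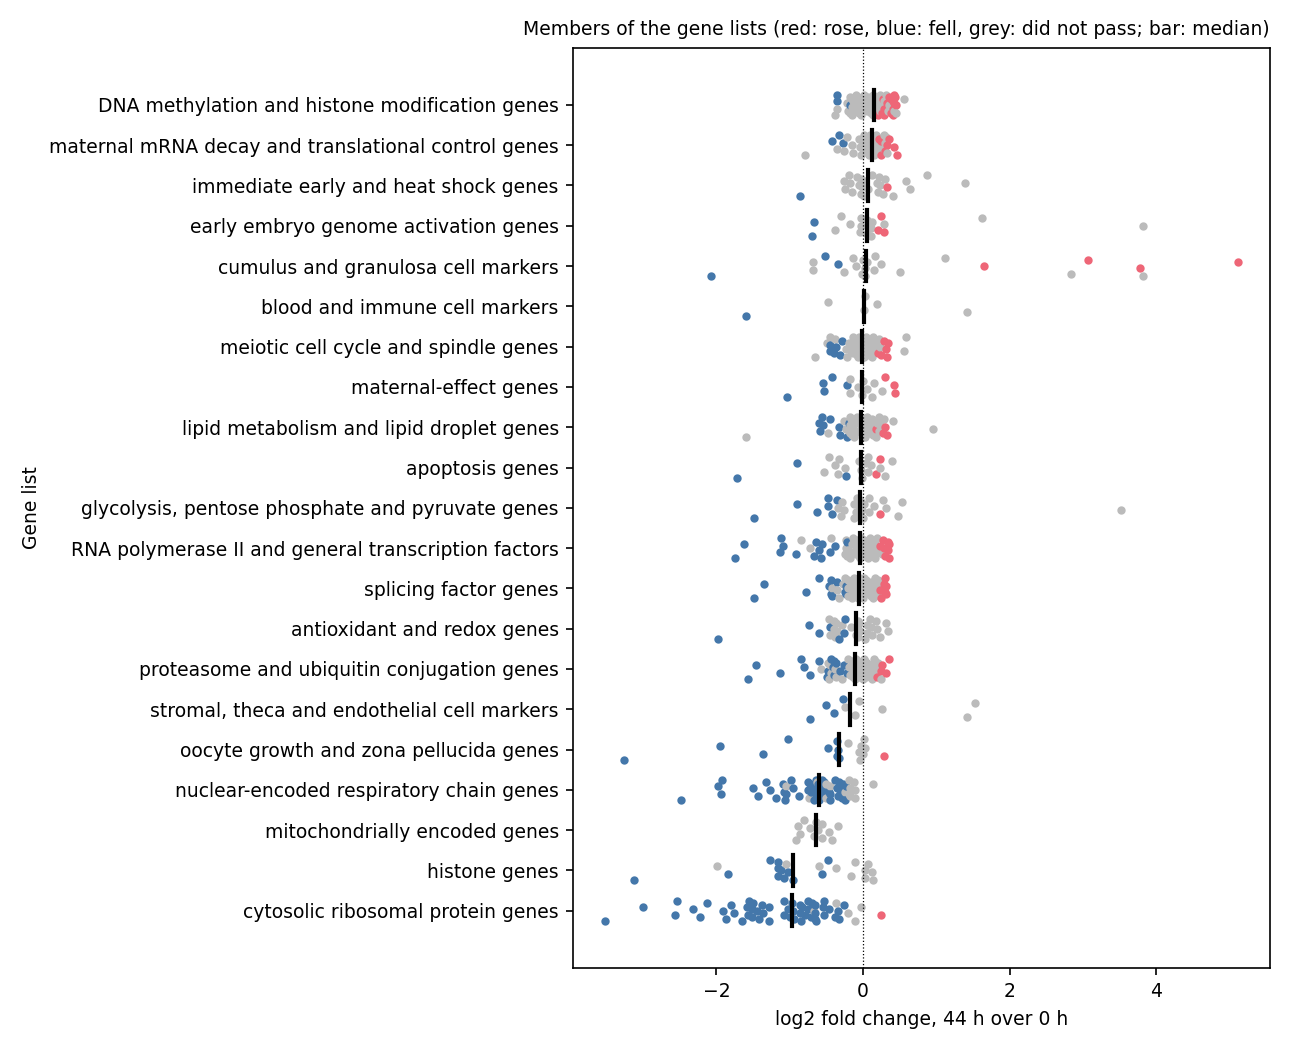
Log2 fold change of each measured member of 21 gene lists, 44 h over 0 h, with red points for genes that rose, blue for genes that fell and grey for genes that did not pass, and a bar at each list's median. The ribosomal protein list has a median of -0.96.

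Of 17 oocyte growth and zona pellucida genes, 9 fell and 1 rose over the course, also when adjusted over the list alone (camera adjusted p = 0.000589, adjusted p = 0.334 with an estimated correlation). ZP4 fell from 1925 ± 183 to 499 ± 64.8 CPM, ZP2 from 1675 ± 179 to 653 ± 89.8 CPM, GDF9 from 1499 ± 51.5 to 1078 ± 16.6 CPM and BMP15 from 5003 ± 420 to 3964 ± 110 CPM. JAG1, a Notch ligand, rose from 2586 ± 102.01 to 3163 ± 43.1 CPM. Among 17 maternal-effect genes, 3 rose and 5 fell, or 3 and 6 adjusted over the list alone. UHRF1, which recruits DNMT1 to DNA, rose from 494 ± 21.0 to 659 ± 21.2 CPM, TET3 from 418 ± 31.9 to 564 ± 34.4 CPM and BTG4 from 403 ± 34.0 to 497 ± 11.5 CPM. OOEP fell from 161 ± 14.9 to 78.5 ± 8.64 CPM and ZAR1L from 1013 ± 60.8 to 692 ± 49.2 CPM, with NLRP5, PADI6 and ZAR1, named after their values were seen. Among 59 meiotic cell cycle genes, 6 rose and 6 fell. CDCA8, of the chromosomal passenger complex, rose from 163 ± 8.54 to 206 ± 7.96 CPM and WEE2 from 1979 ± 35.2 to 2353 ± 77.4 CPM. ESPL1 fell from 498 ± 2.55 to 380 ± 23.6 CPM, BUB1, a spindle checkpoint kinase, from 129 ± 4.90 to 94.1 ± 6.66 CPM, and MOS from 842 ± 13.99 to 687 ± 25.5 CPM. Cyclin B1, CCNB1, stood at 570 ± 13.7 and 561 ± 8.78 CPM and passed neither in the 5 comparisons of 2 times made here nor over time. DNMT1, at 35437 ± 2297 CPM at 0 h, 40352 ± 3019 CPM at 12 h and 31263 ± 2718 CPM at 44 h, passed in none of the 5 comparisons of 2 times made here but did over the 4 times (adjusted p 0.00869 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its fall to 44 h was near the threshold. From 28 h it passed with library totals alone, without a filter, in a fit of only these 2 times and without 28 h replicate 2 (edgeR adjusted p 0.0479 in the last), and from 0 h with library totals alone.

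DNA methylation and histone modification genes rose more often than they fell, 17 against 3 of 76, or 23 against 4 adjusted over the list alone (camera adjusted p = 0.000819, adjusted p = 0.378 with an estimated correlation). Among all tested genes in the longest of 4 classes of gene model length, 412 rose and 250 fell, and this list was not matched on length. KMT2B, a histone H3 methyltransferase, rose from 570 ± 25.1 to 755 ± 34.2 CPM, and KAT8, a histone acetyltransferase, fell from 98.9 ± 9.996 to 76.9 ± 2.58 CPM. UHRF2, named after its values were seen, also fell. Of 56 mRNA decay and translational control genes, 8 rose and 3 fell, with AGO2 rising from 250 ± 6.89 to 335 ± 7.20 CPM and TUT7, a terminal uridylyltransferase, from 50.2 ± 6.17 to 69.4 ± 4.50 CPM (camera adjusted p = 0.00788, adjusted p = 0.611 with an estimated correlation). The poly(A) proteins PABPC1L, from 264 ± 37.8 to 211 ± 13.9 CPM, and TENT2, from 31.4 ± 3.96 to 23.4 ± 1.51 CPM, fell, as did CPEB2, named here after its values were seen. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, single libraries ended the calls of PABPC1L (0 h replicate 4, adjusted p 0.0594) and TENT2 (0 h replicate 3 or 44 h replicate 1 or 4, 0.0501 to 0.0674).

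Of 68 RNA polymerase II and general transcription factor genes, 8 rose and 14 fell over the course. MED15 rose from 382 ± 27.97 to 489 ± 22.1 CPM and TAF4 from 174 ± 9.59 to 221 ± 2.48 CPM, while POLR2F fell from 25.8 ± 4.20 to 7.71 ± 1.01 CPM and GTF2F1 from 184 ± 14.9 to 84.2 ± 11.3 CPM. Splicing factor genes split 7 against 12 of 72, with HNRNPUL1 rising from 189 ± 6.22 to 235 ± 3.602 CPM and SRSF6 falling from 51.1 ± 2.45 to 19.99 ± 1.20 CPM. Proteasome and ubiquitin conjugation genes split 5 against 17 of 70, with PSMD12 rising from 140 ± 16.2 to 174 ± 9.73 CPM, PSMD11 from 116 ± 5.69 to 148 ± 5.85 CPM and UBE2O, PSMD1 and UBE2V1, named after their values were seen, also higher, and PSMB7 falling from 54.5 ± 2.81 to 19.8 ± 2.28 CPM. Adjusted over the list alone, the splits were 8 against 14, 8 against 12 and 6 against 18. None of these 3 lists passed camera (adjusted p 0.464, 0.601 and 0.0627).

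Of 55 lipid genes, 4 rose and 9 fell, the nuclear receptor PPARD rising from 84.5 ± 6.56 to 105.8 ± 4.64 CPM, the acyl-CoA synthetase ACSL3 rising from 1247 ± 55.2 to 1540 ± 68.3 CPM and PLIN2 falling from 207 ± 19.1 to 138 ± 15.6 CPM; SREBF2 and LPIN2, named after their values were seen, also rose. Of 33 glycolysis, pentose phosphate and pyruvate genes, 1 rose and 7 fell (4 and 7 adjusted over the list alone), with transketolase, TKT, falling from 102.2 ± 13.4 to 54.5 ± 0.955 CPM. Of 33 antioxidant and redox genes, 7 fell and 0 rose, the peroxiredoxin PRDX4 from 11.06 ± 1.72 to 2.80 ± 0.537 CPM and GSTM3 from 115 ± 15.1 to 68.8 ± 2.54 CPM. Among 27 immediate early and heat shock genes, KLF4 rose from 50.6 ± 1.14 to 63.1 ± 3.43 CPM and HSPA8 fell from 1004 ± 51.6 to 554 ± 30.4 CPM. The rise among the glycolysis genes was that of RPIA, from 182 ± 12.1 to 213 ± 8.81 CPM, lost in edgeR without 0 h replicate 4 or 44 h replicate 2 (0.0657 to 0.0792). Camera called none of these 4 lists (adjusted p 0.743, 0.464, 0.0919 and 0.504).

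Of 21 apoptosis genes, BCL2L1, which blocks apoptosis, rose from 2303 ± 82.3 to 2606 ± 74.6 CPM and TP53INP1 from 238 ± 22.8 to 279 ± 5.23 CPM. ENDOG fell from 3.92 ± 0.288 to 2.09 ± 0.708 CPM, BAK1 from 1.14 ± 0.523 to 0.341 ± 0.0944 CPM, and cytochrome c, CYCS, named after its values were seen, from 101.2 ± 3.38 to 86.0 ± 4.31 CPM. Of 19 early embryo genome activation genes, 3 rose and 2 fell, or 5 and 2 adjusted over the list alone. GATA4 rose from 149 ± 6.72 to 183 ± 10.9 CPM and UBTF from 103.8 ± 4.05 to 123 ± 4.37 CPM, with OTX2, named after its values were seen. DPPA5 fell from 432 ± 85.3 to 270.5 ± 18.3 CPM and TEAD4 from 5.70 ± 1.31 to 3.50 ± 0.502 CPM. Neither list passed camera (adjusted p 0.936 and 0.464). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, GATA4 and UBTF were not called without 44 h replicate 1 (adjusted p 0.0522 and 0.0690), nor BAK1 or ENDOG without 0 h replicate 2 or 4 or 44 h replicate 1 or 2 (up to 0.138). TEAD4 was lost without those 4 or 44 h replicate 4 (0.0537 to 0.1497), BCL2L1 without 0 h replicate 2 or 3, 28 h replicate 3 or any 44 h library (up to 0.154), and TP53INP1 without 0 h replicate 2 or 4, 12 h replicate 3, 28 h replicate 3 or any 44 h library (up to 0.222).

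Markers of other cell types were measured beside these groups. Of 24 cumulus and granulosa markers, 4 rose and 3 fell between 0 and 44 h. IGFBP5 rose from 0.0414 ± 0.0718 to 1.57 ± 0.141 CPM and INHBA from 1.503 ± 0.718 to 4.72 ± 1.99 CPM, and INHBB fell from 5.49 ± 0.873 to 1.29 ± 1.27 CPM. PTGS2, the prostaglandin synthase of expanding cumulus, had 122 counts in 44 h replicate 1 against 4 and 7 in 44 h replicates 2 and 4. Its edgeR adjusted p of 0.0412 (quasi-likelihood test with Benjamini-Hochberg adjustment) became 0.684 without 44 h replicate 1, and 5 other libraries also ended the call (each 0 h library and 12 h replicates 3 and 5). HSPG2 rose and TIMP3 fell, both named after their values were seen. AMH fell from 209 ± 39.6 to 164 ± 11.13 CPM, which was not called without 0 h replicate 4 or 44 h replicate 2 (0.0996 and 0.0540 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 19 markers below 10 CPM at 0 h summed to 66.6 CPM in 44 h replicate 1, against 37.8 and 39.0 CPM in 44 h replicates 2 and 4. Of 10 stromal, theca and endothelial markers 4 fell (4, and 1 higher, adjusted over the list alone), COL1A2 from 7.54 ± 0.9748 to 4.56 ± 0.299 CPM, TEK from 299 ± 20.8 to 248 ± 15.5 CPM, and TAGLN and PECAM1, named after their values were seen. Without 44 h replicate 1, TEK was not called (edgeR adjusted p 0.0584 with Benjamini-Hochberg adjustment). Of 6 blood and immune markers, CD74 fell from 19.6 ± 4.28 to 6.44 ± 0.189 CPM. For the meiotic, mRNA decay, lipid, antioxidant, immediate early, apoptosis, cumulus and blood lists, adjustment over the list alone gave the same counts. Already at 0 h, 5 cumulus, 4 stromal and 2 blood markers of these lists stood at 10 CPM or more.

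By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2581 genes, 19.9% of those tested, differed between 44 and 0 h, 1077 higher and 1504 lower at 44 h. The median log2 fold change was 0.30 among genes that rose and -0.57 among genes that fell, and only 43 of the risen genes rose by more than 1 on the log2 scale, against 314 that fell by as much. Without 0 h replicate 2 the count was 1706 genes, 607 higher and 1099 lower, and without 44 h replicate 1 it was 618 higher and 1129 lower.

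Genes changed at any time numbered 1705, or 13.1% of those tested, in edgeR's quasi-likelihood test of the 4 times together with Benjamini-Hochberg adjustment, and 1089 without 44 h replicate 1. Between 28 and 0 h, 345 genes differed, 79 higher and 266 lower at 28 h. That count was 128 (34 higher, 94 lower) without 0 h replicate 2, 629 (158, 471) without 0 h replicate 3, 195 (57, 138) without 0 h replicate 4, 202 (45, 157) without 28 h replicate 3 and 127 (33, 94) without 28 h replicate 4. Without 28 h replicate 2, 66 genes were higher and 168 lower. The early and late steps, 12 h against 0 h and 44 h against 28 h, share no library. Across 12977 genes, which are not independent replicates, their log2 fold changes had a Pearson correlation of 0.04 and a Spearman correlation of 0.16. Of the 27 genes changed in the early step, 11 also changed in the late one, all higher at 12 h and lower at 44 h, where independent lists would share 1.27. Both sets of calls came from 1 fit of all libraries, which can favour the same genes of low spread, so the excess was not tested.

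The deposited table carries its own comparisons, made by the authors with DESeq2. At an adjusted p under 0.05 it lists 39 genes for 12 h against 0 h, 92 for 28 h against 12 h, 1064 for 44 h against 28 h, 2467 for 44 h against 0 h and 476 for 28 h against 0 h. Of the genes called here, 24, 32, 600, 2283 and 311 were also in those lists, all with the same direction. For 44 h against 28 h, the deposited comparison had 293 higher and 771 lower genes, against 51 and 558 here.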

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

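The fit without robust estimation was chosen after the data were seen, and the other settings beforehand. Numbers of changed genes stayed within 1.5 times their value under every other scaling, the 1 CPM filter and limma-voom. Exceptions were these. Without a filter on low counts, 64 genes changed between 0 and 12 h and 64 between 12 and 28 h. DESeq2 called 68, 69 and 562 genes for 12 h against 0 h, 28 h against 12 h and 28 h against 0 h. A fit of only the 2 groups compared gave 981 genes for 44 h against 28 h, and could not be made for the test over time. With the replicate number as a replicate block, 28 h against 12 h gave 8 genes, 12 h against 0 h gave 18 higher and none lower. The block also ended 7 list calls by camera: histone, DNA methylation and antioxidant genes for 12 h against 0 h (adjusted p 0.0846, 0.0737 and 0.0799), mitochondrially encoded genes and cumulus markers for 28 h against 12 h (0.431 and 0.0638), and oocyte growth and DNA methylation genes for 44 h against 28 h (0.0638 each). It brought DNMT1 past the threshold for 44 h against 0 h. The labels do not say whether equal numbers mark shared cultures. Residuals correlated over 0.1 in 2 of 10 pairs with the same number, and the main fit left the libraries unpaired. Yet 7 of 11 libraries correlated best with one of their own number, and the median correlation was 0.053 for equal and -0.0151 for different numbers. Each 0 h and 28 h library, times that share all their numbers, correlated best with its own number at the other of these times (0.105, 0.127 and 0.0629). With the block, 28 h against 0 h gave 455 genes, against 345 without it. These values hint that some numbers may share a source, so pairing is not excluded. Gene list calls numbered 23, against 14 by fry and 0 by camera with an estimated correlation (lowest adjusted p = 0.334). Fry passed no list that camera called for 12 h against 0 h or 28 h against 12 h. Its adjusted p at these steps was 0.0535 in both for ribosomal protein genes, and 0.0866 and 0.273 for respiratory chain genes. Nor did fry pass respiratory chain (0.053) and DNA methylation genes (0.192) for 44 h against 28 h. For 44 h against 0 h it did not pass mRNA decay (0.058) and mitochondrially encoded genes (0.203). Some fry calls were of lists that camera did not call. For 44 h against 0 h these were maternal-effect, RNA polymerase II, antioxidant and proteasome genes (fry adjusted p 0.00493, 0.0116, 0.0234 and 0.0179). The others were maternal-effect genes for 28 h against 12 h (0.0223) and RNA polymerase II genes for 44 h against 28 h (0.0142). The correlation of the early with the late step was -0.00339 without a filter. The cause was not tested.

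Leaving out 1 library gave 20 to 261 genes for 12 h against 0 h, 8 to 52 for 28 h against 12 h, 394 to 723 for 44 h against 28 h, 1706 to 2868 for 44 h against 0 h, 127 to 629 for 28 h against 0 h and 1089 to 2168 over time. In each of these, the highest count came without 0 h replicate 3. The correlation of steps ranged from 0.00294 to 0.0824. Of 9, 16, 46 and 80 called named genes in the 4 main comparisons, 4, 10, 14 and 16 lost the call in at least 1 setting, 14, 3, 4 and 2 uncalled ones gained it, and 0 reversed. Pseudocount alternatives did not apply, since the table holds counts.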

Other observations

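The tests of marker levels at 12 h, of scaling on the ribosomal list, of the spread among the strongest rises at 44 h, of families by shared symbol stems and of gene length were chosen only after the results were seen. The genes named in the next 2 paragraphs, and GJA1, HSPG2, TIMP3 and SLC38A3, lie outside the naming rule and were chosen after their values were seen.

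The genes that rose by 12 h did not keep rising to the end of maturation. Of the 23, 11 had their highest mean at 12 h, 12 at 28 h and 0 at 44 h. TRIM56, an antiviral ubiquitin ligase, went from 0.187 ± 0.163 CPM at 0 h to 3.75 ± 0.470 at 12 h, 4.82 ± 0.286 at 28 h and 0.809 ± 0.105 at 44 h. CYP1B1, a cytochrome P450, went from 0.455 ± 0.327 to 4.98 ± 0.530, 6.89 ± 1.01 and 4.73 ± 1.55 CPM, and PEA15, an adaptor of death domains, from 0.759 ± 0.423 to 7.36 ± 1.91, 12.6 ± 1.05 and 4.97 ± 0.510 CPM. SAMD4A, a repressor of translation, was highest at 12 h, at 9.29 ± 1.98 CPM, and stood at 1.36 ± 0.313 CPM at 44 h.

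Families of genes that share a symbol stem, 64 with at least 15 tested members, were tested by camera over 256 family and comparison pairs; 10 passed with the preset correlation and 0 with an estimated correlation. Between 0 and 44 h, 15 of 41 genes of the large mitochondrial ribosomal subunit (MRPL) fell and 0 rose, MRPL52 from 20.3 ± 1.75 to 7.17 ± 1.03 CPM and MRPL55 from 48.5 ± 4.90 to 22.4 ± 2.05 CPM (camera adjusted p = 0.000411, adjusted p = 0.568 with an estimated correlation). Of 27 genes of the small subunit (MRPS), 8 fell, MRPS25 from 109 ± 9.39 to 66.9 ± 2.41 CPM (camera adjusted p = 0.023, adjusted p = 0.513 with an estimated correlation). Ubiquitin-specific proteases (USP) rose for 15 of 46 genes, USP21 from 49.7 ± 5.30 to 64.7 ± 3.65 CPM, and fell for 1, USP39, from 131 ± 6.999 to 104.4 ± 6.84 CPM (camera adjusted p = 0.00152, adjusted p = 0.513 with an estimated correlation). PHD finger genes (PHF) rose for 5 of 17, PHF20L1 from 200.4 ± 19.8 to 263 ± 8.56 CPM. Across 12563 genes, gene model length and log2 fold change had a Spearman correlation of 0.21 for 12 h against 0 h, 0.03 for 28 h against 12 h, 0.12 for 44 h against 28 h and 0.22 for 44 h against 0 h. From 0 to 44 h, in the shortest of 4 length classes, the median change was -0.13 and 618 of 3142 genes fell, and in the longest the median was 0.06 and 250.0 of 3141 fell.

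The loss of ribosomal protein transcripts between 0 and 44 h, a median log2 fold change of -0.96 over 58 genes, was set against technical explanations. Of 10000 random lists of the same gene model lengths, the medians centred on -0.10 and the lowest was -0.38. Of 10000 lists matched on expression, the lowest median was -0.13. Neither length alone nor level alone therefore reached the fall from 0 to 44 h. No list was matched on both, and random lists lack the shared variation of related genes. Length-matched lists were drawn for no other list or step. Lists matched on expression had a median of 0.0132, but scaling puts most genes near 0, so this did not test the scaling. Under each scaling tried, the list median minus that of all genes was -0.96, which a factor per library cannot change. The fall is thus one relative to other genes. Reads shared with processed pseudogenes were not tested and stay open. A loss of these transcripts during maturation may be the cause, as a hypothesis found and tested on the same data.

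The 23 genes higher at 12 h might come from RNA of cumulus or granulosa cells left on the oocytes. The 19 markers of those cells below 10 CPM at 0 h summed at most to 49.8 CPM in a 12 h library and 45.1 CPM in a 0 h library, a ratio of 1.11, while the median fold of the 23 genes was 7.45. TIMP3 and SLC38A3 gave much of that sum at both times, so it can miss a gain of a few CPM in other markers. INHBA stood at 0.890 to 2.29 CPM at 0 h and 3.71 to 4.38 CPM at 12 h, and HSPG2 at 0.162 to 1.16 and 1.22 to 2.20 CPM. Of all 24 markers, 10 had a log2 fold change above 0 at 12 h and 14 below. GJA1, an abundant gap junction gene of cumulus cells, stood at 0.547 CPM or less at 12 h. In the 0 h libraries 5 of the 24 markers reached 10 CPM, and whether this was oocyte or residual cumulus RNA was not tested. Leaving out 1 of the 12 h libraries kept 82.6% of the higher genes without replicate 1, 95.7% without replicate 3 and 91.3% without replicate 5, which argues against a single 12 h library. Whether these transcripts were newly made was not tested, and RNA of a cell type without a list here stays open.

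The 1077 genes higher at 44 h may be RNA that did not change while other RNA was lost, since levels are shares. The SD of their log2 fold changes was 7.01 times their median standard error of 0.0761. This ratio cannot tell whether 1 common factor is exceeded. The SD includes the 43 genes that rose by more than 1, whose median standard error was 0.46, and all these genes were picked by the test. Only 3.99% of the 1077 genes rose by more than 1 on the log2 scale. Small rises cannot be told apart from a loss of other RNA without an added standard. For the 43 genes that rose by more than 1, the SD was 2.69 times the median standard error, but they were picked by the size of their rise, so this decides nothing and the explanation stays open for them too.

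In other splits of the libraries into groups of 3, fits of the 6 libraries of 2 times have only 10 splits, too few for a share under 0.05. The real split and the highest other gave 22 and 3 genes for 12 h against 0 h, 51 and 1 for 28 h against 12 h, 981 and 8 for 44 h against 28 h, 2368 and 0 for 44 h against 0 h and 320.0 and 1 for 28 h against 0 h. For the test over time, only the real split, 1 of 100, gave 1705 genes, and the highest other gave 1170.0. This argues against a chance split of the libraries but cannot separate time from a culture or pool shared by the libraries of a time.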
